A study of Rattus norvegicus with 10 samples.

How the data were processed

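Total RNA from the abdominal aorta of BN and LOU rats was measured on 10 Affymetrix 3′ expression arrays, 5 per strain, after biotin labelling of cRNA, per the labels' protocols. The growth notes state that rats were kept to at most 18 weeks, while the age given with each array is 5 weeks. The extraction notes speak of thoracic and abdominal aorta, and all tissue labels say abdominal. Sex is not given in the labels. Groups were taken from the strain named for each array.

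The deposited values are array intensity on a linear scale, 1 signal per probe set, and how they were scaled is known only from the values. The submitters' processing notes name RMA without a version. The deposited intensity values run from 0 to 22219.9 with a 2% trimmed mean between 200.05 and 200.06 on every array, and their distributions differ between arrays. A log2 table made by RMA would show neither, so the values were taken as linear signals scaled to a common mean. A mean-based scaling leaves arrays dominated by a few strong transcripts slightly lower elsewhere, and median signals ran from 97.4 to 105. The planned test assumed log2 values, so log2(signal) was computed first, with the 4 values of 0 set to 0.1. No array column was left unmapped, and no 2 arrays held the same values (at most 0.358% of values equal).

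Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, 1 coefficient for BN minus LOU, two-sided) over 15866 probe sets after 57 controls were left out, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 10 arrays entered the fit, with strain as the only term. Of the 15866 probe sets, 12783 had 1 gene symbol, 312 had several and 2771 had none in the annotation used here. Symbols were updated through gene identifiers (12748) or accessions (2) in the RefSeq table of the GRCr8 assembly, used only for names and gene order, and 33 were kept as listed. Probe sets with several symbols or none were tested and counted but not named. Each gene was read from the probe set with the highest mean over all arrays, which gave 10411 genes. These entered the list tests and were also fitted alone, and the adjusted p of a named gene is over them.

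The background level of an array was the 95th percentile of 45 bacterial control probe sets, 21.2 to 49.2 over the arrays, a rule chosen after seeing the data. Where a strain had no array above it, the fold is given as a bound, the bright strain's mean log2 signal against the mean of the higher of the background level and the dim signal on each array. Signal over background sets the precision here, since arrays give no counts.

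Before the data were examined, 27 gene lists, the tests and the alternatives were fixed. The named genes are drawn from the 10 with the largest rise and the 10 with the largest fall in BN among genes past the test whose strains do not overlap, up to 4 members of each list with the smallest adjusted p under 0.05, and 13 genes of the artery wall whatever their value. Genes named outside that rule, apart from the control genes, are said to be chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01 and adjusted over 27 lists, with an estimated correlation and the self-contained test fry as alternatives. List means per array, each gene centred over the 10 arrays, were compared with an exact permutation test, whose smallest p for 5 against 5 is 0.00794. Correlations of list means used 100000 permutations.

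The scripts were tested on simulated arrays with the real probe sets' means and spreads, 5 against 5, and 200 changed probe sets among 15866. The test recovered 52% of changes of 1 on the log2 scale, 80.1% of 2, 92.3% of 3 and 96.2% of 4, with 5.63% false calls. With no change it made 0.05 calls per run on average. A list shifted by 0.5 (log2) among 10411 genes was called in 20 of 20 runs at the preset correlation and 19 of 20 with an estimated one, and an unshifted list in 0. The runs took means and spreads from the real probe sets, so this 0 does not measure false list calls among correlated genes. At the preset correlation, other splits of the real arrays called a median of 7 lists and up to 16.

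Alternatives planned were median centring, quantile normalization, leaving out the dimmest 40% of probe sets, a variance trend, array weights, the replicate number as a block, each array left out, 1 probe set per gene, and the mean of a gene's probe sets. Chosen after seeing the data were a floor of 32, a pseudocount of 16, only probe sets above background on all arrays of a strain, the adipocyte list mean as a covariate, and BN array 3 and LOU array 1 left out together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the summaries and plots. Y-linked genes were not analysed here.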

Results

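Gene expression was measured in the abdominal aorta of inbred rats of 2 strains, Brown Norway (BN) and LOU, on Affymetrix arrays that read the 3′ end of transcripts. Each strain had 5 arrays, and the labels gave an age of 5 weeks for every rat. The labels did not say that each array came from its own rat. The p-values of single genes and of list means therefore measure only the spread between these arrays, and the number of arrays limits the precision. Those of the list test at a preset correlation set a list's genes against other genes and do not measure that spread. The test took in 15866 probe sets other than controls, which stood for 10411 named genes. Between 69.7% and 81.9% of the probe sets lay above the level of bacterial control probes on an array. Median signal per array ran from 97.4 to 105. Log2 signals correlated with a median r of 0.93 between arrays of a strain and 0.92 between strains, across probe sets, which are not independent replicates.

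The comparison of BN with LOU addressed the question in the series title, the genetic basis of the arterial traits of the BN rat. The largest difference was in Pla2g2a, a secreted phospholipase A2 found in inflamed arteries. Its signal was 12.5 ± 7.23 (SD, n = 5) in BN and 559.6 ± 224 in LOU, and no BN array was above background, so LOU was at least 15.6-fold higher (limma adjusted p = 0.000122). Echdc2, which encodes a mitochondrial protein related to enoyl-CoA hydratases, was also not above background on any BN array. LOU was at least 5.12-fold higher, with a signal of 172 ± 20.6 (n = 5, adjusted p = 3.5e-05). Vcam1, the endothelial adhesion molecule that binds leukocytes, fell from 527 ± 148 in LOU to 138 ± 27.5 in BN, a 3.77-fold difference (n = 5, adjusted p = 0.00381). Higher in BN were the class I histocompatibility gene RT1-CE16, at 357 ± 62.9 against 32.5 ± 11.5 in LOU, where 3 of 5 arrays were above background, and Retsat, the retinol saturase of fat and liver, at 4016 ± 2194 against 820.3 ± 245 (4.41-fold). Retsat signals of 5733 and 6751 on BN arrays 1 and 2 were the highest, and these arrays also had the highest adipocyte list means of BN, 0.70 and 0.95. LOU array 1, at an adipocyte mean of 0.86, gave a Retsat signal of only 1090.5. BN array 5, with the lowest adipocyte mean of the 10 arrays (−1.07), gave 1454.5, above every LOU array.

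The other 7 of the 10 largest falls in BN were in Prss35, Zp2, RT1-T24-3, Lcp2, Socs2, Chrne and Fntb. LOU was at least 3.67-fold higher for Prss35, a trypsin-like protein, at least 2.15-fold for the egg coat gene Zp2 and at least 1.82-fold for Socs2, an inhibitor of growth hormone signalling. For Lcp2, an adaptor of T cell receptor signalling, the bound was 1.12-fold, and its other probe set differed the same way without passing the test (adjusted p = 0.0851). For Chrne, the epsilon subunit of the muscle acetylcholine receptor, LOU signals of 30.3 ± 11.4 lay too near background for a bound. Fntb, the beta subunit of protein farnesyltransferase, was 144 ± 13.0 in BN and 536 ± 174 in LOU. Of these 10 genes, 9 kept their call when any 1 array was left out, and RT1-T24-3 kept it in 3 of the 10 such fits.

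With each gene read from its brightest probe set, another 7 of the 10 largest rises in BN were in H3c1, C10h16orf89, Ptgr1, Ifitm10, RT1-Bb, Pla2g12a and Syt13. Ptgr1, an enzyme that acts on prostaglandins and leukotrienes, was 199 ± 74.0 in BN and 46.8 ± 24.4 in LOU, where 3 of 5 arrays were above background (adjusted p = 0.0482). Pla2g12a, another secreted phospholipase A2, was 101 ± 12.3 against 30.9 ± 17.2. Pla2g12a and C10h16orf89 had 2 LOU arrays above background and Ifitm10 had 1. The synaptotagmin gene Syt13 was above background on 2 BN arrays and on no LOU array, a bound of 1.22-fold, and the histone gene H3c1 likewise, with signals too low for a bound. RT1-CE16 and RT1-Bb kept their call when any 1 array was left out, and the other 7 genes named as higher in BN here or above kept it in 1 to 3 of the 10 fits.

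**Figure D1:**
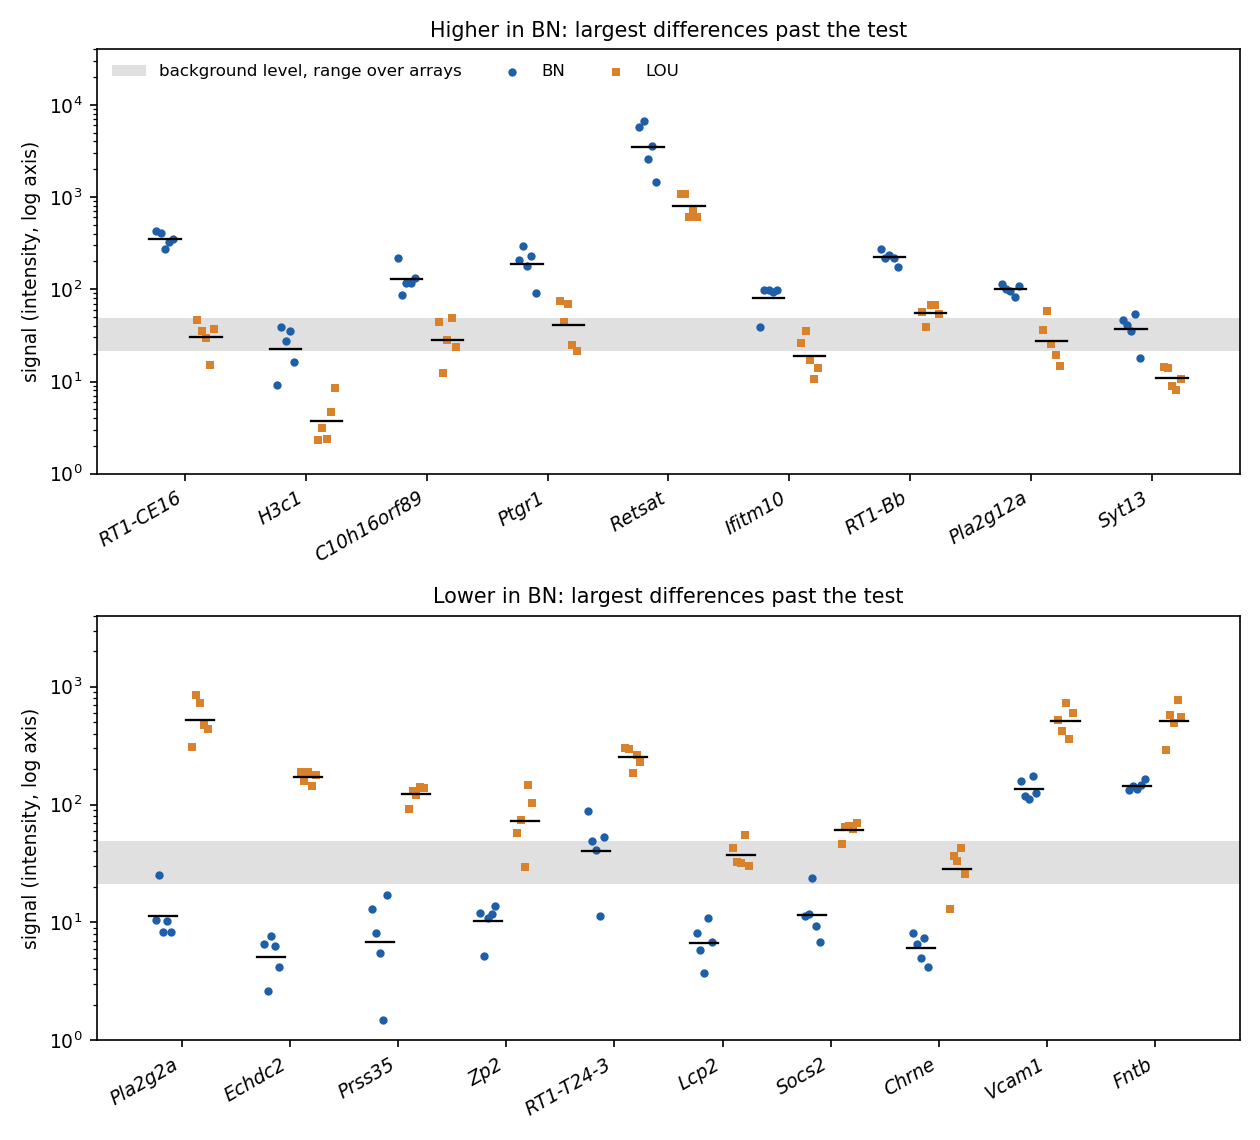
Signal on each array (intensity, log axis) of 9 of the 10 genes with the largest rise in BN and the 10 with the largest fall among those past the test, with 5 BN arrays as circles, 5 LOU arrays as squares and the mean of the log2 signals as a line. The grey band is the range of the background level over the 10 arrays, 21.2 to 49.2, and all 5 BN signals of Pla2g2a and Echdc2 lie within or under that range while all 5 LOU signals lie above it.

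Over all probe sets, 125 of 15866 passed limma's test at an adjusted p of 0.05, of which 39 were higher and 86 lower in BN. At least 2-fold differences numbered 24 higher and 65 lower. Of the 125, 92 had a single gene name, and counted by gene, 29 genes were higher and 61 lower among 10411. In all 125 the 5 BN signals did not overlap the 5 LOU signals. Over all probe sets 4.18% did not overlap, where chance gives 0.794%. In 19 of the 125, 1 strain had no array above background, and in 1 more neither strain had any. Of list members, Bmp6 (−1.38), Tubb5 (−1.30), RT1-S3 (−1.57), Myh1 (1.39 and 1.64) and Jund (BN at least 1.42-fold higher, no LOU array above background), chosen after their values were seen, passed only in probe sets other than the brightest, which stands for the gene in the lists below. Tsc22d4 likewise passed only in such a probe set, with the largest rise of the 125 (log2 4.18, limma adjusted p = 0.00165). Its signal was 410 ± 67.1 in BN and 25.8 ± 15.6 in LOU, with 2 LOU arrays above background. Ddx42 rose by 1.88 in the same way, and both were chosen after their values were seen. Without BN array 2 or 4, or LOU array 2, 3, 4 or 5, the higher probe sets numbered 17 to 21, and without BN array 2 or LOU array 2, 3, 4 or 5 the lower ones numbered 45 to 57. The counts were 78 higher and 175 lower without dim probe sets, 81 and 161 with a variance trend, and, in settings chosen after seeing the data, 60 to 76 and 126 to 187 with dim signals treated otherwise, and 16 and 59 without BN array 3 and LOU array 1, which stood apart in nerve and immune markers. With the replicate number as a block, 23 probe sets passed, 19 of them among the 125, where the data gave a hint that the numbers do not pair.

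Elastic fibre genes were lower in BN as a list, while elastin itself did not differ. Of 17 measured members, 16 had a negative log2 difference, with a median of −0.35, and camera's test against all other genes gave an adjusted p of 0.000877 (adjusted p = 0.744 with an estimated correlation). No member passed the gene test over all genes or adjusted over the list alone. Mfap4, a microfibril protein, was 2713 ± 385 in BN and 3707 ± 612 in LOU (log2 −0.45, adjusted p = 0.237), and the latent TGF-beta binding protein gene Ltbp1 was 991 ± 178 against 1327 ± 97.4 (log2 −0.44, adjusted p = 0.206). Fbln1, a fibulin, gave −0.49, and Efemp1 was the 1 member with a positive value, 1.09. These 4 were chosen after their values were seen. Elastin (Eln) was 9903 ± 981 in BN and 10149.7 ± 595 in LOU (log2 −0.04, SE 0.11, adjusted p = 0.896), and its sign turned with median centring of the arrays. The list means of BN arrays 1, 2 and 3 were −0.35, −0.22 and −0.36, and those of BN arrays 4 and 5, at 0.07 and 0.04, lay inside the LOU range of −0.02 to 0.34 (exact permutation test over the arrays, two-sided, p = 0.0317, adjusted over 27 lists 0.214). Adventitial fibroblast markers, given below, were also lower in BN as a list, with means between −0.19 and −0.08 on the 5 BN arrays. The LOU means ran from −0.10 to 0.40, and LOU array 5, at −0.10, lay inside the BN range.

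**Figure D2:**
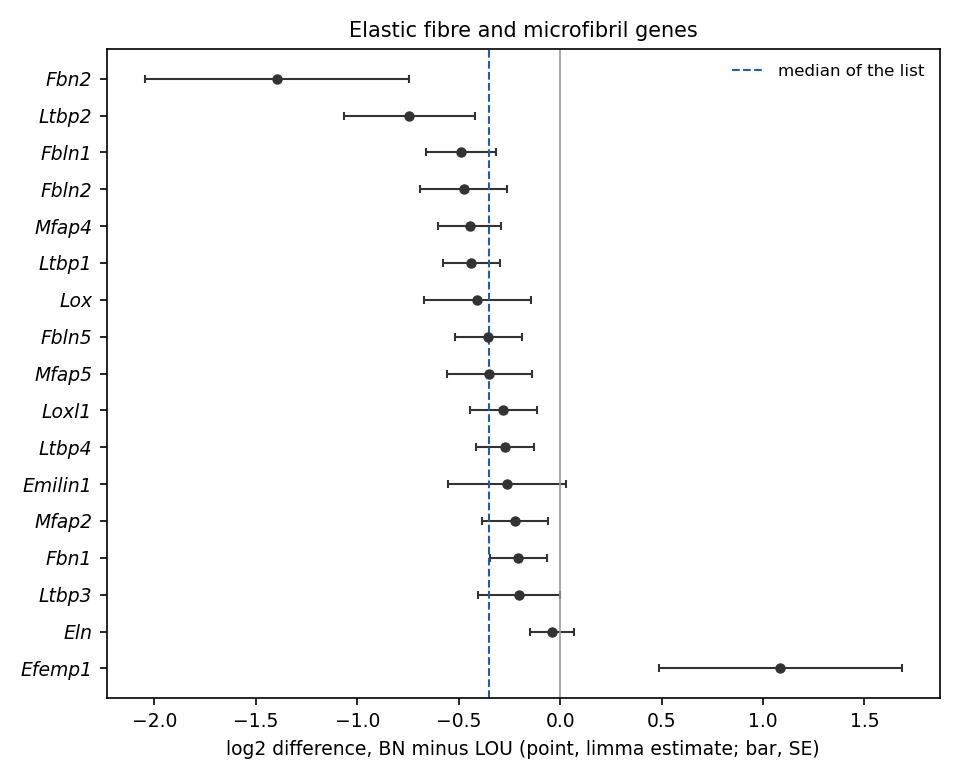
Log2 difference, BN minus LOU, of the 17 measured elastic fibre and microfibril genes, as the limma estimate with its SE, 5 arrays per strain, and a dashed line at the list's median of −0.35. Elastin lies at −0.04 and 15 of the other 16 genes lie below 0, none of them past the gene test.

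Of the other genes fixed for their part in the artery wall, none passed the test. Fibrillin 1 (Fbn1) differed by −0.21 (log2), fibulin 5 (Fbln5) by −0.35 and lysyl oxidase (Lox), which cross-links elastin and collagen, by −0.41, with adjusted p-values of 0.561, 0.382 and 0.542. The fibrillar collagen genes Col1a1 and Col3a1 differed by 0.06 and −0.03, signs that changed with the scaling of the arrays. The second Col1a1 probe set gave −0.41, and a second Fbn1 probe set 0.07. The gelatinase gene Mmp2 differed by −0.35, with a second probe set at −0.00383, and its inhibitor Timp1 by −0.43. The smooth muscle genes Acta2 and Myh11 differed by 0.07 and 0.13. Angiotensin-converting enzyme (Ace) differed by 0.28 and the angiotensin receptor Agtr1a by 0.24, with a second Ace probe set at −0.45. Agtr1a rested on BN array 3, without which the difference was −0.12. Tgfb1 had signals of 132 ± 20.1 in BN and 197 ± 8.79 in LOU that did not overlap (log2 −0.59), with an adjusted p of 0.0585.

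Among 29 measured collagen genes and enzymes that process collagen, Col5a3 rose by 1.21 (log2) and P4ha2, a subunit of collagen prolyl hydroxylase, fell by 0.90. The same 2 passed adjusted over the list alone, and the list did not (median −0.15, adjusted p = 0.205). Another P4ha2 probe set gave 0.06, without LOU array 3 P4ha2 did not pass, and Col5a3 passed in 2 of the 10 fits without 1 array. Among 36 proteoglycans and matrix glycoproteins, osteoglycin (Ogn) fell by 1.53, from 4977 ± 792 in LOU to 1785 ± 571 in BN, and the basement membrane gene Nid1 fell by 0.67. Adjusted over the list alone these and Thbs4 (0.81) and Vcan (−0.88), chosen after their values were seen, passed. A second Ogn probe set gave −1.59 and passed, 2 others gave 0.20 and −0.27 and did not, and the second Nid1 probe set gave −0.14. Nid1 passed in none of the 10 fits without 1 array, and Ogn did not pass without LOU array 3. The list's median was −0.10 (adjusted p = 0.168). Of 34 matrix proteases none passed over all genes, and Mmp9 (lower in BN, where it was not above background, and too dim for a bound) and Furin (0.55) passed adjusted over the list alone, both chosen after their values were seen. That list's median was −0.02 while camera gave the direction up (adjusted p = 0.883). None of the 21 protease inhibitors passed either way (median −0.25, adjusted p = 0.138).

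Adventitial fibroblast markers were lower in BN as a list, with 18 of 25 measured members negative, a median of −0.26 and an adjusted p of 0.0165 (adjusted p = 0.744 with an estimated correlation). Ogn, which is also on this list, passed over all genes. Adjusted over the list alone 6 passed, of which Pi16, Sfrp2, Dpt and Pdgfra differed by −1.08, −1.28, −0.78 and −0.80 and the chemokine gene Cxcl12 by 0.88. Those 5 were chosen after their values were seen. The list did not pass without LOU array 2 or without LOU array 3 (medians −0.17 and −0.20). TGF-beta and BMP signalling genes were lower too, with 25 of 36 members negative, a median of −0.20 and an adjusted p of 0.0308 (adjusted p = 0.744 with an estimated correlation). Bmp4 fell from 255 ± 65.6 in LOU to 99.4 ± 16.6 in BN (log2 −1.34, adjusted p = 0.0137) and passed over all genes. Adjusted over the list alone Bmp4, Tgfb1, Bmp6 (−0.81, with the other probe set given above at −1.38) and Tgfbr1 (−0.60) passed, the last 2 chosen after their values were seen. The list did not pass without BN array 3 (median −0.13) or without LOU array 3 (−0.13).

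Smooth muscle contractile genes did not pass as a list (26 measured, median 0.12, adjusted p = 0.168). Phospholamban (Pln), which restrains the calcium pump of the sarcoplasmic reticulum, fell from 1414 ± 291 to 548 ± 109 (log2 −1.36, adjusted p = 0.00975), its second probe set fell by 1.12, and it was the 1 member to pass over all genes and adjusted over the list alone. Among 57 vasoactive hormones, receptors and channels the adrenergic receptor gene Adra1b fell by 0.67 (adjusted p = 0.0451), which passed in 1 of the 10 fits without 1 array. Adjusted over the list alone it passed with the cyclooxygenase gene Ptgs1 (1.07), chosen after its value was seen, and the list did not (median −0.12, adjusted p = 0.215). Endothelial markers had a median of 0.00 over 25 genes, with a sign that turned when 1 array was left out, and none of them passed (adjusted p = 0.380).

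Genes of oxidative phosphorylation and of fat cells were higher in BN as lists, and single arrays differed widely in them. Oxidative phosphorylation gave the smallest p of the list test at the preset correlation, with 60 of 63 members positive and a median of 0.32. Its adjusted p was 1.19e-09 (adjusted p = 0.744 with an estimated correlation). No member passed alone over all genes or adjusted over the list alone. Brown adipocyte markers had 20 of 24 members positive, a median of 0.44 and an adjusted p of 0.0135, and adipocyte markers 25 of 33, a median of 0.21 and an adjusted p of 0.0444 (adjusted p = 0.744 with an estimated correlation for both). None of their members passed either way. Ucp1, the uncoupling protein of brown fat, chosen after its value was seen, ranged from 1005 to 12345 on BN arrays and from 485 to 5451 on LOU arrays. The means of the adipocyte list were 0.95 on BN array 2, 0.86 on LOU array 1 and, as the lowest of all, −1.07 on BN array 5. Both adipocyte lists lost their call without BN array 1, without BN array 2, without LOU array 3 or without LOU array 4, and the adipocyte list also without BN array 4 (medians 0.23 to 0.30 for brown adipocyte and 0.05 to 0.19 for adipocyte markers). The oxidative phosphorylation means followed the brown adipocyte means over the 10 arrays within strains (Pearson r = 0.92, permutation p = 6.0e-05, Spearman correlation = 0.93, permutation p = 6.0e-05, both adjusted 0.00024 over 4 relations, r = 0.86 without the 2 arrays farthest from the median). Many brown adipocyte markers are themselves mitochondrial genes, so part of this relation is built in. Arrays were permuted within strains of 5, and both permutation p-values are estimates from random draws that lie at the smallest value this can give.

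Nerve and Schwann cell markers were higher in BN as a list, with 26 of 28 members positive, a median of 0.68 and an adjusted p of 5.08e-05 (adjusted p = 0.744 with an estimated correlation). Myelin basic protein (Mbp) rose from 141 ± 46.5 in LOU to 475 ± 195 in BN (log2 1.73, adjusted p = 0.0448), and its other probe set differed by 1.13 (adjusted p = 0.129). Adjusted over the list alone it passed together with the Schwann cell factor gene Sox10, chosen after its value was seen, which no LOU array held above background (BN at least 2.11-fold higher). BN array 3 stood apart with a list mean of 2.59, against −0.39 to 0.23 on the other BN arrays. Without it the median was 0.18 and the adjusted p 0.0407, and Mbp at 1.53 did not pass. Mbp passed in 1 of the 10 fits without 1 array.

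**Figure D3:**
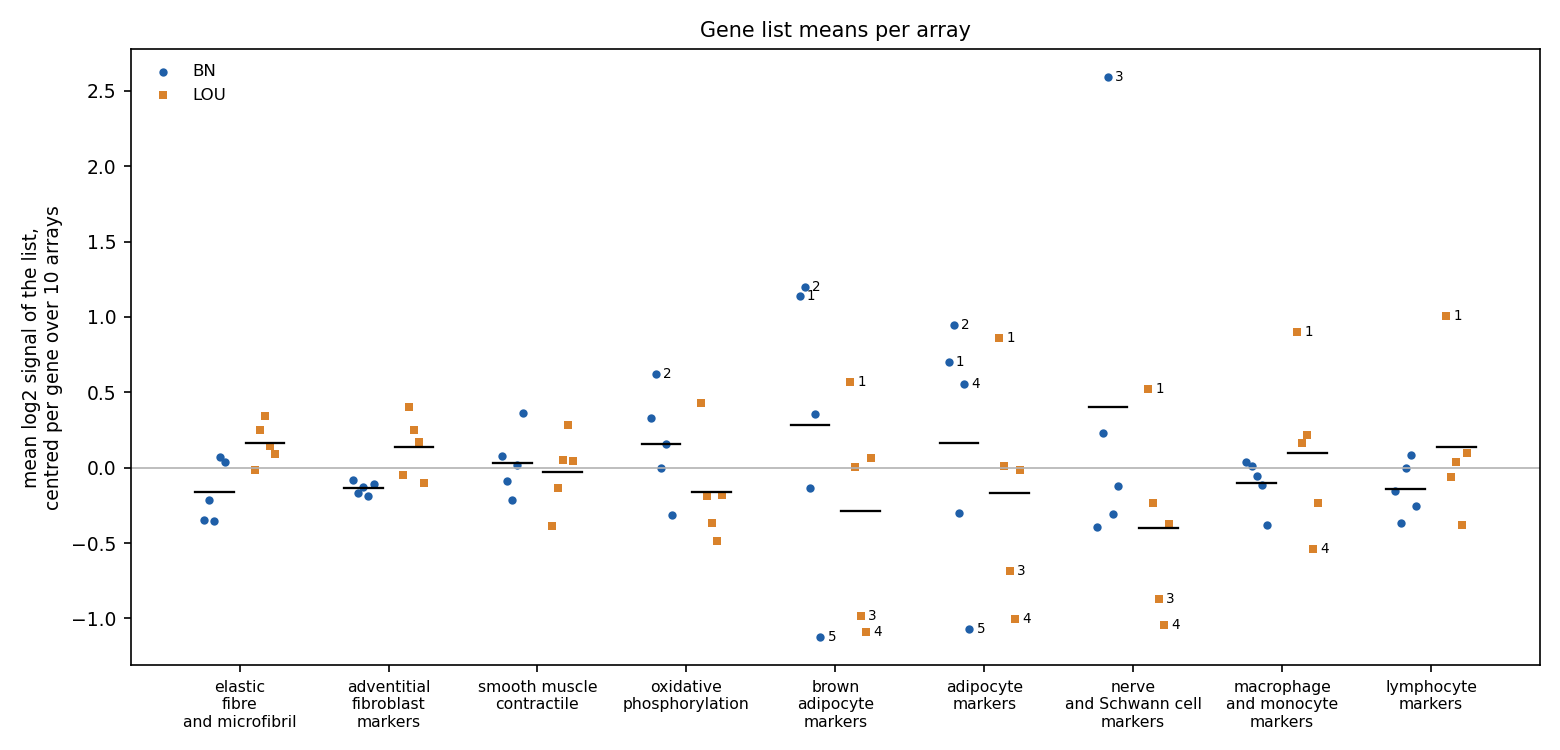
Mean log2 signal of 9 gene lists on each array, each gene centred over the 10 arrays, with BN as circles, LOU as squares and the strain means as lines. Replicate numbers stand beside means beyond 0.5 on either side of 0, and BN array 3 reaches 2.59 in nerve markers while LOU array 1 is at 0.90 in macrophage and 1.01 in lymphocyte markers.

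Histocompatibility genes differed in both directions. Of 31 measured members of the antigen presentation list, RT1-CE16, RT1-Bb and RT1-CE10 (0.93) were higher in BN and RT1-T24-3, RT1-T24-4 (−1.32) and the Fc receptor gene Fcgrt (−0.76) were lower. Fcgrt was chosen after its value was seen. Adjusted over the list alone these 6 passed with the immunoproteasome genes Psmb8 (−0.57) and Psmb9 (−0.66) and the class II gene RT1-Db1 (1.29), the last 3 chosen after their values were seen. RT1-T24-3 was 48.4 ± 27.6 in BN and 256 ± 48.2 in LOU. RT1 genes are near copies of each other and vary between strains, so the gene a probe set reads is uncertain, and a second RT1-Bb probe set went the other way (−1.51, adjusted p = 0.118). The list did not pass (median −0.13, adjusted p = 0.299). Macrophage markers (28 genes, median −0.16) and lymphocyte markers (24 genes, −0.22) did not pass, both with an adjusted p of 0.168 and no member past the test either way. Their means on LOU array 1 were 0.90 and 1.01, above all other arrays, and without that array the macrophage median was 0.03. None of the 26 interferon response genes passed over all genes (median −0.11, adjusted p = 0.258), and Usp18 (−0.61), chosen after its value was seen, passed adjusted over the list alone. None of the 15 mast cell markers (median −0.42, adjusted p = 0.138) or the 15 erythrocyte markers (−0.27, adjusted p = 0.160) passed either way.

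Cell cycle genes were lower in BN, with 30 of 39 members negative, a median of −0.18 and an adjusted p of 0.0308 (adjusted p = 0.744 with an estimated correlation). The cyclin gene Ccnd2 fell from 1189 ± 325 to 403 ± 59.7 (log2 −1.52, adjusted p = 0.0147), the 1 member to pass over all genes and adjusted over the list alone, but not without LOU array 3. The list did not pass without BN array 4, BN array 5, LOU array 4 or LOU array 5 (medians −0.14, −0.18, −0.18 and −0.14). Of 43 immediate early and stress genes, Ier2 fell by 1.37 (adjusted p = 0.0482) and passed in 1 of the 10 fits without 1 array, and 6 passed adjusted over the list alone. The list gave a median of −0.17 (adjusted p = 0.102). Circadian clock genes (15 measured, median −0.17, adjusted p = 0.260), antioxidant and glutathione genes (50 measured, 0.03, 0.192) and cholesterol biosynthesis genes (21 measured, 0.12, 0.138) did not pass, with no member past the test either way. Striated muscle markers (39 measured) had a median of −0.06 and a mean of 0.11, with camera in the direction up (adjusted p = 0.619). None passed over all genes, apart from the 2 other Myh1 probe sets given above, and Mb (3.73, with 2 LOU arrays above background), Myh1 (1.18), Myl1 (0.79) and Tcap (not above background in BN, LOU at least 1.47-fold higher), chosen after their values were seen, passed adjusted over the list alone. Epithelial and mesothelial markers (19 measured) had a median of 0.04 but a mean of −0.09, with camera in the direction down (adjusted p = 0.910), and Krt18 (−2.02, with 2 BN arrays above background), chosen after its value was seen, was the 1 gene to pass adjusted over the list alone.

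In all, 8 of the 27 lists passed camera's test with a preset correlation of 0.01, and none passed when the correlation was estimated from the arrays. The exact permutation test of list means gave its smallest p of 0.0159 for adventitial fibroblast markers, and 0.214 was the smallest value adjusted over the 27 lists. The ratio of 3′ to 5′ control signal, a sign of RNA length, was 1.56 ± 0.133 in BN and 1.62 ± 0.238 in LOU for Gapdh (n = 5, exact permutation test, two-sided, p = 0.730). For beta-actin it was 4.36 ± 0.704 and 4.28 ± 0.302 (p = 0.905, exact). Xist, the transcript of the inactive X chromosome, gave signals of 1 to 3.1 on the 10 arrays, under the background level, and the strains' difference gave an exact p of 0.659 (adjusted over the 3 control measures 0.905). Signals that low do not settle the sex of the rats, so this test could not show a difference in sex between the strains.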

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

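Chosen only after the result was seen were the tests of fat cells, of brown adipocyte RNA, and of the elastic fibre list against smooth muscle and against fibroblasts. Dixon's test for 1 array far from the others of its strain was passed in 11 of 150 groups of 5 arrays, where chance passes about 7.5 (1 in 20). Among list means, BN array 3 stood apart in nerve markers at 2.59 (the others −0.39 to 0.23), BN array 2 in mast cell markers at 0.34 (−0.40 to −0.19), BN array 5 in histocompatibility genes at −0.34 (0.01 to 0.06) and LOU array 1 in cholesterol biosynthesis at 0.17 (−0.18 to −0.09). Among log2 signals on BN arrays, the arrays far from the others were array 1 for Ifitm10 at 5.29 (6.53 to 6.64), array 2 for Pla2g2a at 4.66 (3.05 to 3.38), array 2 for Zp2 at 2.38 (3.43 to 3.80) and array 3 for Agtr1a at 8.43 (6.36 to 6.88). On LOU arrays they were array 1 for Socs2 at 5.53 (5.95 to 6.11), array 1 for Ccnd2 at 9.35 (10.23 to 10.56) and array 2 for Nid1 at 10.48 (10.21 to 10.24).

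The first pattern weighed is the set of calls in single probe sets, where 125 passed and 89 of them differed by at least 2-fold. If the strains did not matter, other splits of the arrays would call as many, but of 100 splits only the real 1 reached 125 calls, 89 calls of at least 2-fold or 90 gene calls (1 of 100 each time), and the highest other counts were 3, 3 and 2. Fat on some arrays as the whole cause is argued against by the 111 of 125 probe sets that kept their call with the adipocyte mean as a covariate. Sequence variants between the strains under the 3′ probes stay open and cannot be told apart from a difference in RNA, since the median ratio of a gene's other probe sets to the called one was 0.361 (95% interval 0.0872 to 0.824), from only 7 of 55 genes with a usable second probe set. Those 55 were called in their brightest probe set. Genes called only in another probe set, where the brightest did not pass, did not enter the ratio. A difference in transcript level between the strains, in any of the cells of the sample, was not tested apart from these and stays open.

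The second pattern is the oxidative phosphorylation list, higher in BN in the list test at the preset correlation. Its means over the arrays did not pass (exact permutation test, p = 0.190, adjusted 0.471). Chance is not excluded for the number of lists called, since 46 of 100 splits, the real 1 included, called at least as many as the 8 of 27 found, with up to 16 in another split. More brown adipocyte RNA on some BN arrays goes with the values, since the list rose by 0.378 per unit of the brown adipocyte mean within strains (SE 0.0629). That slope took the strain difference of 0.316 down to 0.0997 (SE 0.102). Many brown adipocyte markers are themselves mitochondrial genes, so both results are partly built in. They do not tell brown fat from mitochondria in other cells. With the adipocyte list as covariate, the median of 0.18 still passed the list test. How much fat was left on the vessel and a strain difference in fat or mitochondria are both open, and neither was tested.

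The third pattern is the elastic fibre list, lower in BN. If attached tissue diluted the wall, smooth muscle genes would fall alike, but their median was 0.12, and the elastic mean less the smooth muscle mean differed by −0.384 between the strains (exact p = 0.0476, adjusted over 3 comparisons 0.0714). With the adipocyte mean as a covariate the elastic median was −0.26 and passed the list test (adjusted p = 0.0055). As to chance, 46 of 100 splits, the real 1 included, call at least as many lists in all, which is no test of dilution. With 5 arrays per strain the adjusted exact value misses the threshold. Dilution as the whole cause thus cannot be told apart from a change in elastic genes. Fewer adventitial fibroblasts on the BN arrays also cannot be told apart from it, since fibroblast markers without shared members fell by 0.256 (exact p = 0.0159, adjusted 0.0476) and the elastic mean less this mean differed by −0.0672 (exact p = 0.579). A strain difference in the wall itself stays open and was not tested.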

How the results depend on the processing

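Settings chosen after seeing the data were the floor of 32, the pseudocount of 16, the limit to probe sets above background, the adipocyte covariate, and BN array 3 and LOU array 1 left out together. The 39 higher probe sets became 78 without dim probe sets, 81 with a variance trend, 60 with the floor, 60 with the pseudocount, 76 above background only and 16 without those 2 arrays, and the 86 lower ones 175, 161, 144 (pseudocount) and 187 (above background only). The 24 higher by at least 2-fold became 41 with the trend, 15 with 1 probe set per gene and 13 without the 2 arrays, and the 65 lower ones 40 with 1 probe set per gene. Fewer tests entered in the settings without dim or background probe sets, and for the others the cause was not tested. Of the 125 calls, 107 were shared under median centring, 116 under quantile normalization, 121 with the trend, 123 with array weights, 104 with the floor, 122 with the pseudocount and 63 without the 2 arrays. All those still tested were kept without dim probe sets (92) and above background only (111). With unadjusted p under 0.05 there were 2103 probe sets, where chance gives 793.3. With 1 array left out the counts ran from 17 to 36 higher and 45 to 91 lower, and at 2-fold from 13 to 30 and 43 to 69. With the replicate block, 10 probe sets were higher and 13 lower, all by at least 2-fold, and 19 of these were among the 125. Arrays with the same number correlated at 0.15, −0.02, −0.07, −0.05 and −0.03, and of the 10 arrays only BN array 1 correlated best with its own number, a hint from the data that the numbers do not pair. The scale shifted the median of all probe sets by −0.03, 0.02 and −0.00 (log2) as deposited, median centred and quantile normalized.

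The 8 lists past the test became 0 with an estimated correlation, where all gave an adjusted p of 0.744, and 0 with the self-contained test, and ran from 4 (without LOU array 3) to 11 with 1 array left out. Self-contained adjusted p-values were 0.198 for elastic fibre (median −0.35), TGF-beta (−0.20), adventitial fibroblast (−0.26) and cell cycle genes (−0.18), 0.421 for nerve (0.68) and oxidative phosphorylation (0.32), 0.598 for brown adipocyte (0.44) and 0.731 for adipocyte markers (0.21). Adipocyte markers also missed the threshold under median centring (0.26), quantile normalization (0.24), the mean of probe sets (0.21) and the floor (0.30), brown adipocyte markers with the adipocyte covariate (0.15) and cell cycle genes with the trend (−0.18). Newly past it were collagens (−0.25) and proteoglycans (−0.13) under quantile normalization, smooth muscle (0.18), macrophage (−0.33), lymphocyte (−0.38) and erythrocyte markers (−0.30) with the adipocyte covariate, and erythrocyte markers without dim probe sets (−0.48). So were immediate early genes under median centring (−0.12), without dim probe sets (−0.19) and above background only (−0.18), and antioxidant genes without the 2 arrays (0.0936). Signs turned for matrix proteases under median centring (0.0356), quantile normalization (0.00774), array weights (0.00879) and the pseudocount (0.00150). They also turned for endothelial markers without dim probe sets (−0.0106), with array weights (−0.000919), the pseudocount (−0.0116) and the covariate (−0.0149), and for macrophage markers without the 2 arrays (0.00482). The same holds for striated muscle without dim probe sets (0.11) and for epithelial markers above background only (−0.26) and with the covariate (−0.0264). The cause was not tested for any of these.

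With 1 array left out, elastic fibre (−0.42 to −0.25), nerve (0.18 to 0.98) and oxidative phosphorylation lists (0.21 to 0.48) kept their side of the threshold each time. Calls were lost at least once for TGF-beta (−0.26 to −0.13), adventitial fibroblast (−0.34 to −0.17), adipocyte (0.0536 to 0.48), brown adipocyte (0.23 to 0.73) and cell cycle lists (−0.21 to −0.14). Calls appeared for proteoglycans (−0.15 to −0.0560; without BN array 5 or LOU array 1), smooth muscle (0.0440 to 0.18; without BN array 3 or LOU array 4), antioxidant genes (0.0206 to 0.0873; without LOU array 1) and immediate early genes (−0.25 to −0.10; without BN array 2, LOU array 1 or LOU array 2). Without LOU array 4 they appeared for macrophage (−0.38 to 0.0321), lymphocyte (−0.39 to −0.0183) and erythrocyte markers (−0.40 to −0.19), and without BN array 5 for cholesterol biosynthesis (−0.0731 to 0.20). Signs turned for matrix proteases (−0.11 to 0.0485), endothelial (−0.0610 to 0.14) and epithelial markers (−0.0709 to 0.20), macrophage markers and cholesterol biosynthesis. Over all settings, list values stayed on their side and sign in 552 cases, missed the threshold in 39, newly passed in 23 and turned in 30. Why was not tested, beyond 1 array fewer.

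Of 686 values of the 32 genes past the test that the naming rule picked under the other settings, 499 passed, 187 did not and 0 turned. Pla2g2a and RT1-CE16 passed in all 22 settings and Echdc2 in all 21 that tested it, since it was among the dim probe sets left out in 1. Among genes that did not pass, signs turned for Eln (0.0115 under median centring, 0.0128 without the 2 arrays, −0.0761 to 0.000399 with 1 array left out), Col3a1 (0.0213, 0.0197, −0.0874 to 0.0349) and Col1a1 (−0.0684 under quantile normalization, −0.18 with the mean of probe sets, −0.0309 to 0.16). They turned for Ace with the mean of probe sets (−0.0837), Agtr1a (−0.0771 without the 2 arrays, −0.12 to 0.40) and Acta2 (−0.0105 to 0.13). Tgfb1 passed without dim probe sets (adjusted p = 0.0261), with the trend (0.0412), the floor (0.0232), the pseudocount (0.0441) and above background only (0.0319). The 3′ to 5′ ratios (−0.0862 to 0.0383 for Gapdh, −0.0649 to 0.0934 for beta-actin, log2) and Xist (−0.34 to 0.0662) also turned with 1 array left out. The cause was not tested. Signal over background limits the folds of genes not above background in 1 strain to bounds, and differences in dim probe sets are the least precise.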

Other observations

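The genes named in this and the next paragraph were chosen after their values were seen, apart from Ier2. BN array 3 had high signals of sympathetic nerve cell genes, with 16 of 28 nerve list members at least 10-fold above the median of the other 9 arrays. Dopamine beta-hydroxylase (Dbh) gave 3146 there, 64.1-fold above that median, tyrosine hydroxylase (Th) 2608, neuropeptide Y (Npy) 5674, the synaptic gene Snap25 1723 and the neuronal filament gene Prph 2380. LOU array 1 had the next highest Dbh signal, 286, and the highest leukocyte markers, with 24 of 52 macrophage and lymphocyte list members at least 2-fold above the other 9 arrays' median. Ptprc, the common leukocyte antigen, gave 163 there against 18.1 to 34.5 elsewhere, Coro1a 216 and lysozyme (Lyz2) 1371. Myoglobin (Mb), of striated muscle, gave 888, 1229, 321, 141 and 111 on BN arrays 1 to 5 and 10.8 to 67.6 on LOU arrays.

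Fos and Egr1 are switched on within minutes of stimulation. Fos gave 200, 57, 2023, 2693 and 767 on LOU arrays 1 to 5 and 25.1 to 103 on BN arrays (log2 −3.66, adjusted p = 0.135). Egr1 gave 1070 to 8312 on LOU and 232 to 741 on BN arrays, without overlap (log2 −2.99, adjusted p = 0.0575). Adjusted over the 43 list members alone, both passed with Ier2, Dusp6 (−0.95), Ier3 (−1.18) and Egr2 (−1.01). Atf3 varied widely within both strains, from 116 to 1636 on BN and from 392 to 3394 on LOU arrays. Of the 4 heat shock genes of the list, Hsph1 (1.15), Hspa1a (1.12) and Hspb1 (0.94) lay above 0 and Dnajb1 (−0.19) below, and none passed either way.

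If stretches of the genome differ between the strains, genes with calls would lie near each other, a test written before its result was seen. Without the antigen presentation list and RT1 genes, 83 called genes could be placed in gene order, and 11 pairs lay within 5 measured genes of each other. Those genes were left out by name and not by position, so others of the histocompatibility region could stay in. Random sets matched on signal gave 3.25 pairs on average and 6 at their 95th percentile (permutation test with 10000 draws, p = 0.0012). Of the 11 pairs, 5 changed the same way, among them Zp2 with Crym, Vcam1 with Lrrc39, and Prss35 with Snx14. The others changed in opposite ways, as where Retsat rose and its neighbour Tgoln2 fell, so direction lends the pairs no weight. Lyrm1, Zp2 and Crym lie together and pair with each other, so the pairs are not all independent. Crym, Lrrc39, Lyrm1, Snx14 and Tgoln2 were chosen after their values were seen. These pairs are consistent with variants that act on nearby genes, but probes for neighbouring genes could also share a stretch rich in sequence variants, and the test does not separate the 2.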
